A study of Populus yunnanensis and Populus davidiana with 24 samples.

How the data were processed

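The series holds 24 RNA sequencing libraries of poplar cutting stems, 12 from Populus yunnanensis and 12 from Populus davidiana. Per the labels' protocols, messenger RNA was collected from the stems and cDNA libraries were sequenced on an Illumina platform. The deposited table gives 1 FPKM value per gene and library, made by the authors, per the file headers. The aligner, the counting tool and the genome build are not given in the sources used here, and the annotation is given only through the form of the gene identifiers. Of 43836 identifiers, 40865 carry a chromosome number from 1 to 19, 2085 carry the letter T of an unplaced scaffold, and 886 are assembled loci named MSTRG. Identifiers other than those of assembled loci start with Potri and end in version 3.1. The table does not pair identifiers with names, and no genome was used here, so the gene lists prepared before the data were examined (the WOX family, auxin, cytokinin, wound, cell wall and tissue marker lists among them) could not be matched and were not analysed here. FPKM depends on the gene length used and on the total of mapped fragments, so a change in abundant genes moves all others, and fragments of a species that differs from the reference can align less well.

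Each library was put in its group by its title, which gives the species, the time and the replicate number. Whether replicates came from separate plants is not given in the sources used here, so the p-values measure the spread between these libraries, which may be technical. All columns of the table were assigned to a library.

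Genes with at least 1 FPKM in at least 3 libraries (24643) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. One mean was fitted per species and time over all 24 libraries, which left 16 residual degrees of freedom and 1 shared spread per gene, with a trend of the variance on the mean. P-values were adjusted by the Benjamini-Hochberg method within each of 15 comparisons, and genes with an adjusted p under 0.05 are called changed. A log2 change is on the log2(FPKM + 1) scale, which understates the change of low genes. Species differences are P. davidiana minus P. yunnanensis. Genes to be named were chosen by a rule fixed before the data were examined. For each comparison against 0 h, each species comparison at 0 and 120 h and the interaction at 120 h, they were the 2 genes with the highest rise and the 2 with the deepest fall among called genes with a mean of at least 5 FPKM in a compared group and, except for the interaction, no overlap between the replicates. Counts called independent are the product of the lengths of both lists divided by 24643. Genes at 0 in every library of a group are said to be listed at 0, and no fold is given against them.

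Relative depth was estimated in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. It was the most frequent ratio, across genes, of low values (0.03 to 0.3 FPKM) between a library and P. yunnanensis 96 h replicate 1. As FPKM is scaled to mapped fragments, it is a depth of mapped fragments and not of all those sequenced. Values scaled by it were then checked as whole multiples of the smallest step of their gene, read from its lowest values. In 1220 genes with a readable step, 83.3% of 4583 values were whole multiples within a tolerance of 0.1, where 20.0% would be by chance. The absolute number of fragments stays unknown, so no counting interval is given. Figures were drawn with matplotlib 3.10.9.

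Replicates share numbers across groups. Deviations from the group means were correlated between libraries of the same number in 12 comparisons, and in 1 of them, P. davidiana at 48 h against 0 h, all 3 correlations were above 0.1 (0.297, 0.287 and 0.256). The labels do not say what the number marks. The main fit has no block, and a fit with the number as a block was an alternative.

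The fit was tested on simulated data for 24643 genes at 120 h against 0 h, with 100 genes changed by 2-fold and 100 by 4-fold. The changed genes were drawn only from the more abundant ones, so recovery was not measured for low genes. With equal spread in every group, 4.72% of the calls were false in the P. yunnanensis comparison and 3.10% in the P. davidiana comparison. With the spread of each group as measured these shares were 41.1% and 2.31%, and with the spread weighted by group 7.29% and 7.41%.

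The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter beyond a value above 0, a filter of 5 FPKM, median ratio scaling, quantile normalization, rescaling to TPM, no variance trend, only the compared groups in the fit, an absolute log2 change of at least 1, a replicate block and leaving out each library in turn. The spread weighted by group, rescaling without the 20 most abundant genes, a higher minimum for genes listed at 0 in one species and the correlation between species under median ratio scaling were added after seeing the data.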

Results

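Gene expression was measured in stems of leafless, budless cuttings taken from annual branches of 2 poplar species, Populus yunnanensis and Populus davidiana. Stems were sampled at 0, 48, 96 and 120 h, with 3 replicates per species and time, which gave 8 groups and 24 libraries. The series title names differences in rooting between poplars and the WOX family of homeobox transcription factors. The expression table held FPKM values, that is, fragments scaled to the length of the gene and to the total of mapped fragments. It listed 43836 gene models, of which 10268 were at 0 in every library and 24643 reached 1 FPKM in at least 3 libraries and were tested. The table gave gene identifiers without names, so genes are named by identifier alone, with at most 2 that rose and 2 that fell for each comparison. WOX genes were not analysed here by name.

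The number of reads behind each library is unknown. The ratios of low FPKM values between libraries gave relative depths of 0.620 to 1.11 times that of the P. yunnanensis 96 h replicate 1 library. The mean relative depth was 0.948 ± 0.0871 (SD, n = 12) in P. yunnanensis and 0.730 ± 0.0662 (SD, n = 12) in P. davidiana. At 0 h, 20198 ± 1131 genes reached 1 FPKM in P. yunnanensis and 18663 ± 457 did in P. davidiana (SD, n = 3 each). At 120 h these numbers were 21213 ± 599 and 19241 ± 572 (SD, n = 3 each). No pair of replicate libraries held identical values.

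The species separated the libraries along the first principal component, which held 51.3% of the variance, and time ran along the second, which held 13.6%. Pearson correlations of log2(FPKM + 1) across genes ranged from 0.702 to 0.805 between libraries of different species. They ranged from 0.767 to 0.976 within P. yunnanensis and from 0.853 to 0.983 within P. davidiana. The 0 h libraries of P. yunnanensis differed most from one another, with correlations of 0.869 to 0.896 and a residual SD of 0.73 on the log2 scale. In the other 7 groups the residual SD lay between 0.41 and 0.55. As deposited, the median log2 change over all tested genes against 0 h was 0.10, 0.33 and 0.34 at 48, 96 and 120 h in P. yunnanensis. In P. davidiana it was 0.0032, 0.027 and 0.083 at these times. Rescaling the libraries by the median ratio of their genes brought the P. yunnanensis medians to -0.0087, 0.00088 and -0.012. The numbers of genes that rose and fell under another scaling are given where it turned which of them was larger or moved the share of rises by over 10 percentage points.

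**Figure D1:**
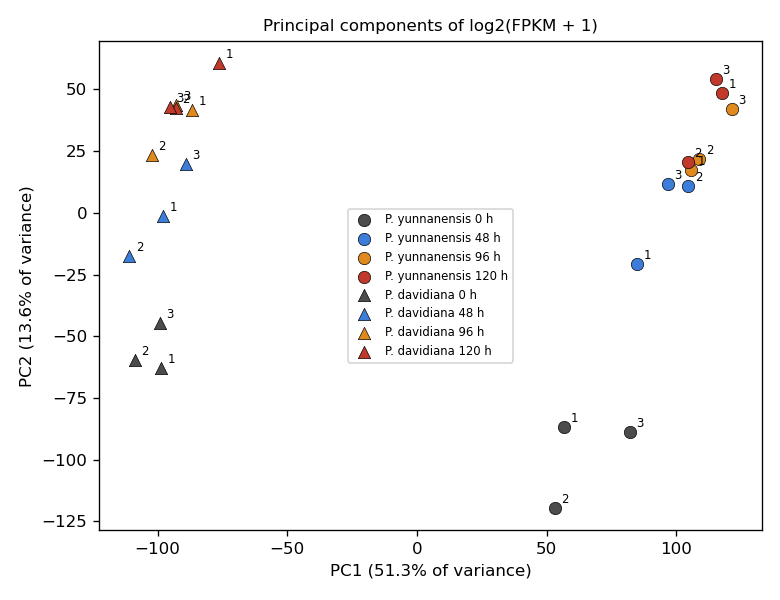
First and second principal components of log2(FPKM + 1) over the 24643 tested genes, one point per library, with the replicate number beside it. Circles are P. yunnanensis and triangles P. davidiana, coloured by time. The species lie on opposite sides of the first component (51.3% of variance), and the 0 h libraries of both species lie lowest on the second (13.6%).

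The first comparison asked which genes changed in P. yunnanensis stems by 48 h. Potri.T012400.v3.1, on an unplaced scaffold, rose from 30.8 ± 53.0 FPKM at 0 h to 831 ± 502 FPKM at 48 h (SD, n = 3 each), a log2 change of 7.04 (SE 1.09, adjusted p = 0.000191). Potri.010G142800.v3.1 rose from 8.35 ± 6.86 to 1234 ± 1189 FPKM (SD, n = 3 each), a log2 change of 6.53 (SE 1.22, adjusted p = 0.0011). Potri.003G165000.v3.1 went from 128 ± 63.9 to 0.655 ± 0.733 FPKM (SD, n = 3 each) and fell by 6.24 on the log2 scale (SE 0.69, adjusted p = 5.64e-06). Potri.006G139400.v3.1 went from 214 ± 87.2 to 3.27 ± 0.714 FPKM (SD, n = 3 each) and fell by 5.58 on the log2 scale (SE 0.51, adjusted p = 8.81e-07). In all, 3844 of 24643 genes changed at an adjusted p under 0.05 with limma, 2245 upwards and 1599 downwards. With median ratio scaling 1739 rose and 2151 fell, and without 0 h replicate 2 1661 rose and 2012 fell. The count was 1378 with the spread weighted by group, 167 from the 6 compared libraries alone and 2433 without 48 h replicate 3. With those 6 libraries alone the calls of Potri.T012400.v3.1 (adjusted p = 0.135, range over its alternatives 4.92e-08 to 0.135) and Potri.010G142800.v3.1 (adjusted p = 0.0683, range 0.000605 to 0.0683) ended.

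At 96 and 120 h the genes with the highest rises in P. yunnanensis were the same pair at both times, taking genes of at least 5 FPKM whose replicates did not overlap. Potri.001G346800.v3.1 rose from 0.229 ± 0.243 FPKM at 0 h to 322 ± 49.0 at 96 h and 397 ± 87.8 at 120 h (SD, n = 3 each), log2 changes of 8.05 (SE 0.60, adjusted p = 4.72e-08) and 8.34 (SE 0.60, adjusted p = 2.8e-08). Potri.001G083200.v3.1 rose from 0.0547 ± 0.0474 to 163 ± 17.4 and 328 ± 117 FPKM (SD, n = 3 each), log2 changes of 7.28 (SE 0.64, adjusted p = 3.11e-07) and 8.21 (SE 0.64, adjusted p = 6.43e-08). Potri.006G166800.v3.1 stood at 24.6, 81.0 and 1311 FPKM in the 3 libraries at 0 h and at 1.49 ± 0.315 FPKM (SD, n = 3) at 120 h. It fell by 6.33 on the log2 scale at 96 h (SE 0.92, adjusted p = 7.2e-05) and fell by 5.82 at 120 h (SE 0.92, adjusted p = 0.000126). Potri.003G165000.v3.1 was still low at 96 h, at 1.02 ± 1.09 FPKM (SD, n = 3), and fell by 5.999 on the log2 scale against 0 h (SE 0.69, adjusted p = 6.07e-06). Potri.018G046600.v3.1 went from 475 ± 272 to 13.1 ± 18.8 FPKM at 120 h (SD, n = 3 each) and fell by 5.85 (SE 0.95, adjusted p = 0.000168). The number of changed genes was 6753 at 96 h, with 5245 higher and 1508 lower, and 8899 at 120 h, with 6811 higher and 2088 lower.

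The excess of rises in P. yunnanensis depended on the scaling. With median ratio scaling 2406 genes rose and 2592 fell at 96 h, and 3261 rose and 3474 fell at 120 h. Quantile normalization gave 3204 rises and 2634 falls at 96 h, and 4520 rises and 3307 falls at 120 h. The 4 genes named at each time kept their direction and their call under both. Among the other settings, weighting the spread by group gave 3682 genes at 96 h and 5445 at 120 h, and the 6 compared libraries alone gave 1505 and 2447, where Potri.006G166800.v3.1 at 96 h had an adjusted p of 0.0526 (range over its alternatives 6.94e-06 to 0.0526). Requiring an absolute log2 change of at least 1 gave 4444 genes at 96 h. Leaving out 96 h replicate 3 gave 4261 genes at 96 h, and leaving out 120 h replicate 1 gave 5879 at 120 h. In data simulated with the spread of each group as measured, only 100 genes each, drawn from the more abundant ones, changed by 2-fold and 4-fold. The shared spread recovered 44% and 82% of them at 120 h against 0 h, and 88 of its 214 calls (41.1%) were false. With the spread weighted by group 16% and 73% were recovered and 7.29% of the calls were false.

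Between 48 and 120 h, a contrast without the 0 h means whose spread was still shared with the 0 h libraries, 461 genes changed in P. yunnanensis, 415 upwards and 46 downwards. With median ratio scaling 240 rose and 104 fell, and with quantile normalization 322 rose and 115 fell. The count was unstable. It was 174 with a pseudocount of 0.1 and 256 with a filter of 5 FPKM, and limma on the 6 compared libraries alone called 0 genes, with 3777 at an unadjusted p under 0.05 where 1232 would arise by chance. It was 131 without 48 h replicate 1, 90 without 120 h replicate 1, 1616 without 120 h replicate 2 and 159 without 120 h replicate 3.

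In P. davidiana at 48 h, Potri.007G120400.v3.1 rose from 1.47 ± 1.28 to 109 ± 23.6 FPKM (SD, n = 3 each), a log2 change of 5.57 (SE 0.61, adjusted p = 3.75e-05). Potri.016G057600.v3.1 rose from 3.42 ± 2.60 to 327 ± 252 FPKM (SD, n = 3 each), a log2 change of 6.09 (SE 1.65, adjusted p = 0.0422). Potri.002G206400.v3.1 went from 66.5 ± 22.3 to 1.62 ± 1.36 FPKM (SD, n = 3 each) and fell by 4.75 (SE 0.53, adjusted p = 3.94e-05). Potri.015G074600.v3.1 went from 55.6 ± 35.4 to 1.56 ± 0.991 FPKM (SD, n = 3 each) and fell by 4.34 (SE 0.48, adjusted p = 3.75e-05). Of 969 changed genes, 501 were higher and 468 lower at 48 h. Which was larger turned with the scaling, at 593 higher and 626 lower with median ratio scaling, 532 and 559 with quantile normalization, 449 and 487 with TPM scaling, and 501 and 548 after rescaling without the 20 most abundant genes. It also turned with no filter on low values (449 and 483), with an absolute log2 change of at least 1 (368 and 382), and without 0 h replicate 1 (398 and 405), 0 h replicate 2 (224 and 271), 48 h replicate 1 (458 and 500) or 48 h replicate 3 (182 and 228). The call of Potri.016G057600.v3.1 ended without any 1 of the 6 libraries (adjusted p = 0.063 to 0.167) and with no filter on low values (adjusted p = 0.061), in a range over its alternatives of 0.01 to 0.167. The 6 compared libraries alone called 25 genes, and there the calls of Potri.016G057600.v3.1 (adjusted p = 0.0657), Potri.002G206400.v3.1 (adjusted p = 0.063, range 1.32e-05 to 0.063) and Potri.015G074600.v3.1 (adjusted p = 0.0734, range 6.92e-06 to 0.0734) ended. The count was 495 without 0 h replicate 2, 604 without 0 h replicate 3, 632 without 48 h replicate 2 and 410 without 48 h replicate 3.

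At 96 and 120 h Potri.007G120400.v3.1 had the highest rise in P. davidiana among called genes of at least 5 FPKM whose replicates did not overlap, reaching 618 ± 109 FPKM at 96 h and 1076 ± 445 at 120 h (SD, n = 3 each). Its log2 changes against 0 h were 8.07 (SE 0.61, adjusted p = 4.44e-07) and 8.81 (SE 0.61, adjusted p = 6.35e-08). Potri.016G057600.v3.1 rose to 1675 ± 1676 FPKM at 96 h (SD, n = 3), a log2 change of 7.99 (SE 1.65, adjusted p = 0.00268). Potri.004G109200.v3.1 was listed at 0 in all 3 libraries at 0 h and reached 175, 231 and 321 FPKM at 120 h (adjusted p = 1.23e-05). Potri.004G106600.v3.1 went from 398 ± 336 FPKM to 1.16 ± 0.511 at 96 h and 2.56 ± 0.607 at 120 h (SD, n = 3 each). It fell by 6.88 (SE 0.85, adjusted p = 3.22e-05) and fell by 6.15 (SE 0.85, adjusted p = 5.08e-05). Potri.013G129800.v3.1 went from 89.5 ± 36.8 FPKM to 0.782 ± 0.617 and 0.871 ± 0.343 (SD, n = 3 each), and fell by 5.64 (SE 0.52, adjusted p = 1.5e-06) and fell by 5.52 (SE 0.52, adjusted p = 1.09e-06).

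The number of changed genes in P. davidiana was 3661 at 96 h, with 2136 higher and 1525 lower, and 4867 at 120 h, with 3131 higher and 1736 lower. At 120 h median ratio scaling gave 2672 rises and 2383 falls, and quantile normalization 2501 and 2499. In simulated data with the spread of each group as measured, changes at 120 h were set in the more abundant genes alone. Of these, 41% of 2-fold and 86% of 4-fold changes were recovered, and 2.31% of the calls were false. At 96 h the 6 compared libraries alone called 2343 genes, and the count was 2393 without 0 h replicate 1 and 2331 without 96 h replicate 3. At 120 h it was 3117 without 0 h replicate 1 and 4336 from the 6 compared libraries alone. Which species had more calls turned with the fit. With the spread weighted by group 5405 genes at 96 h and 7060 at 120 h were called in P. davidiana, against 3682 and 5445 in P. yunnanensis. The compared libraries alone gave 1505 and 2447 in P. yunnanensis. At 48 h P. yunnanensis kept more calls under both, at 1378 against 1263 and 167 against 25.

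Between 48 and 120 h 1478 genes changed in P. davidiana, 1129 upwards and 349 downwards. With median ratio scaling 1032 rose and 592 fell, and with quantile normalization 846 rose and 524 fell. The count was 2707 with the spread weighted by group and 444 from the 6 compared libraries alone. It was 279 without 48 h replicate 2, 738 without 120 h replicate 1, 823 without 120 h replicate 2 and 544 without 120 h replicate 3.

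**Figure D2:**
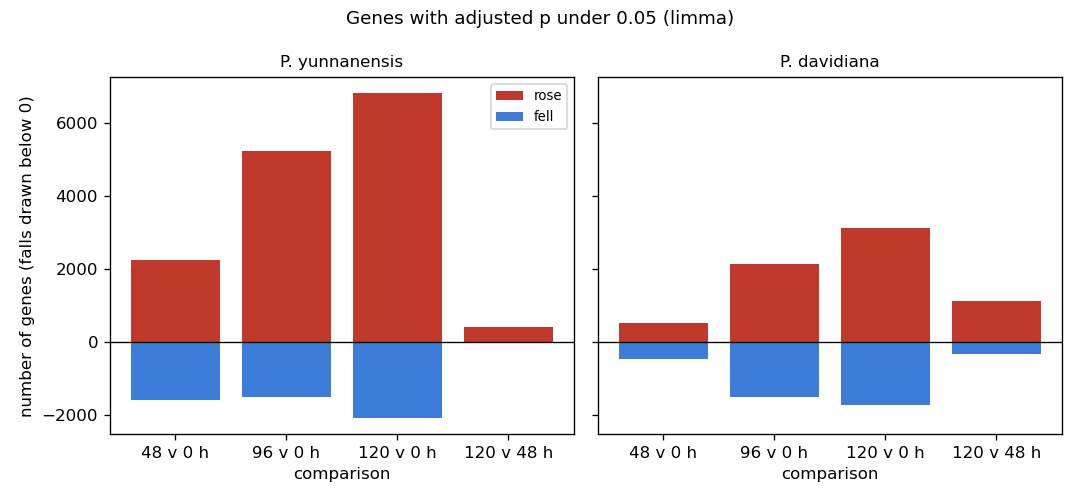
Number of genes with an adjusted p under 0.05 in each time comparison, in P. yunnanensis (left) and P. davidiana (right), with rises drawn above 0 and falls below 0. At 120 h against 0 h 6811 genes rose and 2088 fell in P. yunnanensis, and 3131 rose and 1736 fell in P. davidiana. Median ratio scaling gave 3261 and 3474 in P. yunnanensis, and 2672 and 2383 in P. davidiana. With the spread weighted by group, 5445 genes in all were called at 120 h in P. yunnanensis and 7060 in P. davidiana.

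The species comparison asked which genes differed between cuttings of the poplars at one time. At 0 h Potri.015G092000.v3.1 stood at 857 ± 14.3 FPKM in P. davidiana and at 1.64 ± 1.61 in P. yunnanensis (SD, n = 3 each), a log2 difference of 8.52 (SE 0.40, adjusted p = 2.61e-12). Potri.017G051100.v3.1 was listed at 0 in all 3 P. yunnanensis libraries at 0 h and at 301, 97.5 and 205 FPKM in P. davidiana (adjusted p = 3.19e-11). Potri.003G154400.v3.1 was listed at 0 in all 3 P. davidiana libraries at 0 h and at 385, 166 and 169 FPKM in P. yunnanensis (adjusted p = 7.43e-13). Potri.011G025400.v3.1 stood at 0.464 ± 0.329 FPKM in P. davidiana and at 466 ± 498 in P. yunnanensis (SD, n = 3 each), a log2 difference of -7.77 (SE 0.55, adjusted p = 9.57e-10). Of 10209 genes that differed at 0 h, 4682 were higher in P. davidiana and 5527 lower. Quantile normalization turned this to 5924 higher and 4995 lower, TPM scaling gave 5209 and 5155, and leaving out P. yunnanensis 0 h replicate 3 gave 4735 and 4575. The 6 compared libraries alone gave 6122 genes.

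At 120 h Potri.005G132201.v3.1 was listed at 0 in all 3 P. yunnanensis libraries and at 219, 182 and 285 FPKM in P. davidiana (adjusted p = 1.55e-13). Potri.002G218500.v3.1 stood at 450 ± 121 FPKM in P. davidiana and at 1.46 ± 0.622 in P. yunnanensis (SD, n = 3 each), a log2 difference of 7.51 (SE 0.44, adjusted p = 5.16e-11). Potri.T012400.v3.1, which rose in P. yunnanensis, stood at 2.12 ± 1.82 FPKM in P. davidiana and at 789 ± 389 in P. yunnanensis (SD, n = 3 each), a log2 difference of -8.04 (SE 1.09, adjusted p = 6.3e-06). Potri.010G012100.v3.1 stood at 3.68 ± 1.60 and 1186 ± 334 FPKM (SD, n = 3 each), a log2 difference of -8.01 (SE 0.72, adjusted p = 3.28e-08). In all, 11556 genes differed at 120 h, 3909 of them higher in P. davidiana and 7647 lower. Median ratio scaling gave 4952 higher and 6319 lower, and quantile normalization 5412 and 5710. A fragment that aligned less well in one species would move these values too, and the reference genome is not given in the sources used here.

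At 48 h 10336 genes differed between the species, 4253 higher in P. davidiana and 6083 lower, and at 96 h 11292 differed, 3436 higher and 7856 lower. Quantile normalization gave 5632 higher and 5172 lower at 48 h and 5597 and 5198 at 96 h, and median ratio scaling gave 4672 and 6500 at 96 h. The differences at 0 h and at 120 h, which share no libraries, ran together across genes (Pearson r = 0.608, Spearman rho = 0.583, genes not being independent replicates). At both times 2138 genes were higher in P. davidiana, against 743 for independent lists, and 3692 were lower, against 1715. The calls at both times share the spread of each gene over all libraries, which the counts for independent lists leave out. Another 279 genes differed in opposite directions at 0 and 120 h.

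**Figure D3:**
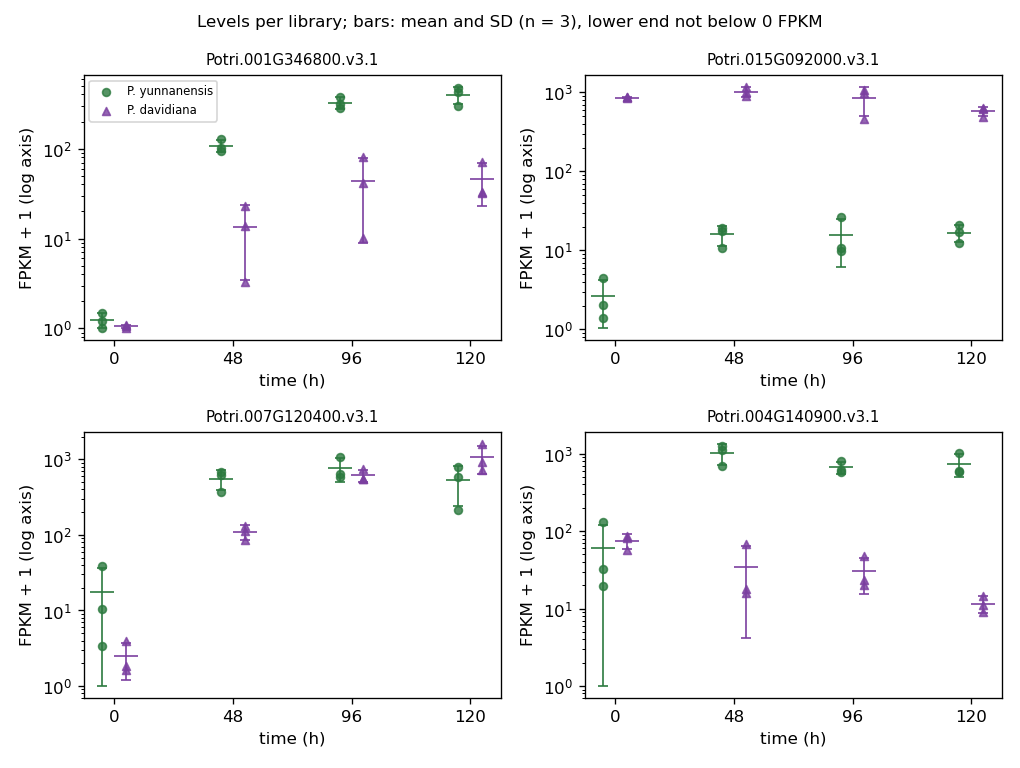
FPKM + 1 on a log axis against time (times evenly spaced) for 4 named genes, one point per library, with bars for the mean and SD (n = 3, lower ends stopped at 0 FPKM). Potri.001G346800.v3.1 reached 397 ± 87.8 FPKM at 120 h in P. yunnanensis, Potri.007G120400.v3.1 reached 1076 ± 445 in P. davidiana, Potri.015G092000.v3.1 stood at 857 ± 14.3 in P. davidiana and 1.64 ± 1.61 in P. yunnanensis at 0 h, and Potri.004G140900.v3.1 stood at 734 ± 242 in P. yunnanensis and 10.6 ± 2.83 in P. davidiana at 120 h.

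The species by time interaction tested whether the change against 0 h differed between the species, as the P. davidiana change minus the P. yunnanensis change. At 120 h Potri.010G089800.v3.1 stood at 1095 ± 293 FPKM in P. davidiana, from 19.97 ± 13.9 at 0 h, and at 16.2 ± 19.5 in P. yunnanensis, from 375 ± 572 (SD, n = 3 each). Its changes differed by 9.38 on the log2 scale (SE 1.49, adjusted p = 0.000489). Potri.007G111800.v3.1 went from 0.422 ± 0.429 to 246 ± 81.0 FPKM in P. davidiana and from 14.2 ± 20.8 to 4.89 ± 6.36 in P. yunnanensis (SD, n = 3 each), a difference of 8.43 (SE 1.60, adjusted p = 0.00192). Potri.004G140900.v3.1 went from 74.0 ± 16.01 to 10.6 ± 2.83 FPKM in P. davidiana and from 59.4 ± 60.1 to 734 ± 242 in P. yunnanensis (SD, n = 3 each), a difference of -6.74 (SE 0.79, adjusted p = 3.65e-05). Potri.T012400.v3.1 went from 0.387 ± 0.402 to 2.12 ± 1.82 FPKM in P. davidiana and from 30.8 ± 53.0 to 789 ± 389 in P. yunnanensis (SD, n = 3 each), a difference of -6.09 (SE 1.54, adjusted p = 0.0124). The last call ended with a pseudocount of 0.1 (adjusted p = 0.0572) and with the 12 compared libraries alone (adjusted p = 0.0615), in a range over its alternatives of 1.62e-05 to 0.0615.

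The interaction was called for 467 genes at 48 h (207 positive and 260 negative), 2239 at 96 h (762 and 1477) and 3679 at 120 h (1425 and 2254). With median ratio scaling the signs were 330 positive and 281 negative at 48 h, 1281 positive and 938 negative at 96 h, and 2070 and 1441 at 120 h. Quantile normalization gave 279 and 340 at 48 h, 1198 and 1169 at 96 h, and 1877 and 2183 at 120 h. At 48 h the signs were 349 and 237 without P. yunnanensis 0 h replicate 2, and 178 and 168 without P. davidiana 48 h replicate 2. Of the 3679 genes at 120 h, 2054 passed the time test in P. yunnanensis alone, 1108 in P. davidiana alone, 90 in the same direction in both, 238 in opposite directions and 189 in neither. This division was not repeated with the spread weighted by group. That weighting gave 5445 time calls at 120 h in P. yunnanensis and 7060 in P. davidiana. The 12 compared libraries alone gave 99, 1229 and 2191 genes at the 3 times. At 48 h the count was 252 with a pseudocount of 0.1 and 188 with the spread weighted by group, and it was 820 without P. yunnanensis 0 h replicate 3, 266 without P. davidiana 0 h replicate 2, 287 without P. yunnanensis 48 h replicate 3 and 286 without P. davidiana 48 h replicate 1. At 96 h it was 1428 without P. davidiana 0 h replicate 1 and 1435 without P. yunnanensis 96 h replicate 3. At 120 h it was 2124 without P. yunnanensis 120 h replicate 1 and 2225 without P. davidiana 120 h replicate 3.

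The time changes of the species, which share no libraries, were also set side by side. At 120 h 1290 genes rose in both, against 865 for independent lists, and 457 fell in both, against 147. Another 238 genes changed in opposite directions. Of these, 108 rose in P. yunnanensis and fell in P. davidiana, against 480 for independent lists, and 130 did the reverse, against 265. Across all tested genes the log2 changes at 120 h had a Pearson r of 0.297 and a Spearman rho of 0.293, and 61.5% had the same sign. At 48 h 220 genes rose in both (46 for independent lists) and 169 fell in both (30), with r = 0.447 across genes. At 96 h 836 rose in both (455) and 374 fell in both (93), with r = 0.344.

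**Figure D4:**
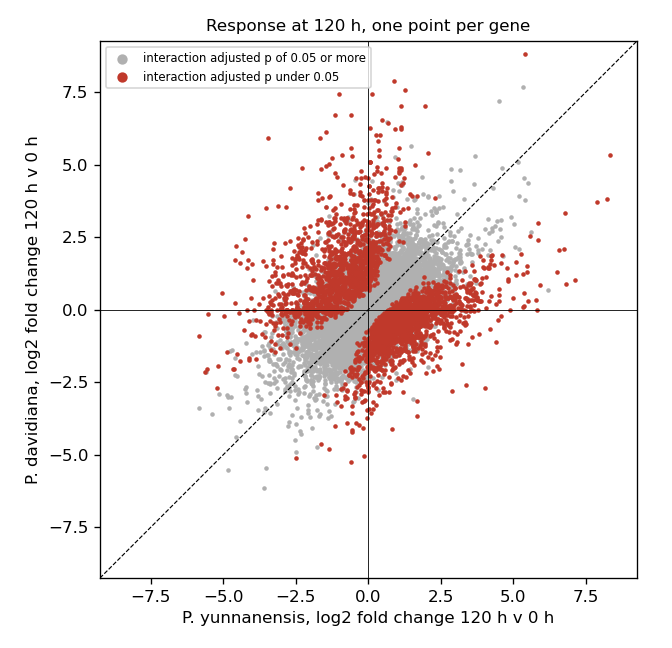
Log2 change at 120 h against 0 h in P. davidiana (vertical axis) against that in P. yunnanensis (horizontal axis), one point per tested gene, with the line of equal change dashed. The 3679 genes with an interaction at an adjusted p under 0.05 are red and the others grey, and r over all genes was 0.297.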

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

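The tests of depth at 120 h and in replicate 1 and the count of genes at 0 set against alignment were chosen after the results were seen, and the rescaling without the 20 most abundant genes was added after seeing the data. The response to time differed between the species, by a test of the difference itself, for 467 genes at 48 h, 2239 at 96 h and 3679 at 120 h. Among the 100 splits drawn of the libraries at each time, 9, 4 and 4 called at least as many genes, the real one included, and the highest other splits called 2126, 7566 and 9567 genes. These splits exchange times within a species, so they test for no time response in either species and not for equal responses in both. Splits that keep the response of one species whole, or that turn it round, call many genes by construction. At 48 h splits that exchanged part of the libraries in both species called 1207 and 624 genes, also more than the real 467. For these reasons the splits do not decide on chance for the interaction at any of the 3 times.

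The differences of log2 change at 120 h, P. davidiana minus P. yunnanensis, were 9.38 for Potri.010G089800.v3.1, 8.43 for Potri.007G111800.v3.1, -6.74 for Potri.004G140900.v3.1 and -6.09 for Potri.T012400.v3.1. In the 3 P. yunnanensis libraries at 0 h these genes stood, in this order, at 1034, 64.9 and 25.0 FPKM, at 38.2, 2.96 and 1.45, at 31.1, 18.6 and 128, and at 0.514, 0 and 92.0. A 0 h level that varied between libraries thus enters all 4 differences. The calls of the first 3 genes held in all 23 alternatives for each, with limma adjusted p up to 0.00716, 0.00807 and 0.00117. The call of Potri.T012400.v3.1 ended in 2 of 23.

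Each comparison between 2 groups has 10 splits of its 6 libraries, too few for a share under 0.05, and only 1 split, the real one, called as many genes in each. Every other split mixes libraries of both groups, so a real difference enters its spread and lowers its count. Low counts in the other splits thus decide nothing on chance. In P. yunnanensis the real count and the highest other were 3844 and 897 at 48 h, 6753 and 73 at 96 h, 8899 and 41 at 120 h, and 461 and 286 between 48 and 120 h. In P. davidiana they were 969 and 6, 3661 and 2, 4867 and 0, and 1478 and 1. Between the species they were 10209 and 130 at 0 h, 10336 and 0 at 48 h, 11292 and 0 at 96 h, and 11556 and 0 at 120 h.

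In P. yunnanensis at 120 h 76.5% of the called genes rose. A few very abundant genes taking a smaller part of the FPKM total were examined as a cause. After rescaling without the 20 most abundant genes by mean over all 24 libraries, 73.8% rose, so those 20 genes alone did not give the excess. Other genes abundant mainly at 0 h were not covered by this rescaling. A greater depth at 120 h is argued against by mean relative depths of 120 h and 0 h that differed by 0.0147, within their SDs of 0.109 and 0.0516. Median ratio scaling gave 48.4%, but it centres the median gene by construction and decides nothing on the cause. The rule written for the abundant genes asked for the excess to hold, or to end, under both rescalings, so it gave no verdict. Letting the first rescaling alone decide departed from that rule. A broad change in RNA composition and a true rise of many genes may both give the excess, and neither was tested.

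The 0 h libraries of P. yunnanensis varied most, with mean correlations to their own group of 0.883, 0.880 and 0.894 in replicates 1, 2 and 3, and the 20 most abundant genes taking 9.71%, 22.96% and 15.7% of the FPKM total. Potri.013G100800.v3.1, chosen after its values were seen, stood at 75.9, 40153 and 29641 FPKM in them. A P. davidiana library in place of replicate 1 is argued against by 141 of 142 genes (99.3%) seen in the other P. yunnanensis libraries alone being above 0 in it, and in replicate 2 146 of 150 such genes were above 0. Replicate 1 lay 0.297 of the way from the other 0 h libraries to the 48 h mean over 3500 genes. The 48 h libraries lay at 0.993 to 1.01, near 1 by construction, since their mean ends the way. Libraries not used to draw the way lay at 0.959 to 0.992 at 96 h and at 0.945 to 0.980 at 120 h. The position of replicate 1 argues against a 48 h library in its place, though no 48 h library was held out. The relative depth of replicate 1 (0.868) lay within the range of the other P. yunnanensis libraries (0.832 to 1.11). The way to 48 h was drawn from replicates 2 and 3 and so was no test of replicate 2, and a difference between cuttings may remain as an explanation and was not tested.

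Genes listed at 0 in every P. davidiana library and at 1 FPKM or more in every P. yunnanensis library numbered 133, against 13 the other way round. At the estimated depths, with the smallest step taken as 1 fragment, the lowest number expected over the P. davidiana libraries was 37.3 fragments. That 100% of the genes would have 3 or more was fixed by the filter of 1 FPKM at these depths, so this share was no test. The expected numbers argue against lower depth alone only as far as the step, read from genes of at most 0.6 FPKM, holds for these genes. No excess of blocks was detected among the 98 of them placed on chromosomes, with 4 genes that had a fellow within 5 places against a median of 2 in 10000 random draws (one-sided permutation p = 0.352). Fragments that fail to align at diverged genes may give such a list, and so may genes missing from P. davidiana. These are not the only possible explanations, and they cannot be told apart from the 133 genes without reads or a genome.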

How the results depend on the processing

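The spread weighted by group and the rescaling without the 20 most abundant genes were added after seeing the data. With only the compared groups in the fit, counts at 48, 96 and 120 h against 0 h were 167, 1505 and 2447 in P. yunnanensis, and 0 between 48 and 120 h (3777 at an unadjusted p under 0.05), where 3844, 6753, 8899 and 461 were reported. In P. davidiana they were 25 at 48 h, 2343 at 96 h, 4336 at 120 h and 444 between 48 and 120 h. They were 6122 between the species at 0 h and 99, 1229 and 2191 for the interactions. These fits have fewer libraries and so fewer degrees of freedom, and estimate the spread from those libraries alone. With the spread weighted by group counts were 1378, 3682 and 5445 in P. yunnanensis and 188 for the interaction at 48 h. In P. davidiana this weighting gave 5405 at 96 h, 7060 at 120 h and 2707 between 48 and 120 h. A pseudocount of 0.1 gave 174 genes between 48 and 120 h in P. yunnanensis and 252 for the interaction at 48 h, a filter of 5 FPKM gave 256 for the former, and an absolute log2 change of at least 1 gave 4444 at 96 h in P. yunnanensis. The cause was not tested for the pseudocount, and the last 2 settings pass fewer genes by construction. Other counts stayed within 1.5 times of the reported ones under the remaining settings.

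Leaving out 1 library gave 2433 to 3696, 4261 to 7318, 5879 to 9142 and 90 to 1616 genes in P. yunnanensis (48, 96 and 120 h, and 120 against 48 h). In P. davidiana it gave 410 to 958, 2331 to 3015, 3117 to 4232 and 279 to 1597. Between the species it gave 8645 to 10160 at 0 h, 8447 to 9531 at 48 h, 9258 to 10320 at 96 h and 9307 to 11023 at 120 h, and for the interactions 266 to 820, 1428 to 3323 and 2124 to 4696. The correlation of the changes at 120 h between the species ranged from 0.236 to 0.362, with an SD of 0.034 over these fits, and was 0.297 under median ratio scaling and 0.319 for genes of at least 5 FPKM. The lowest of 90 for 120 against 48 h came without 120 h replicate 1 and the highest of 1616 without 120 h replicate 2.

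With the replicate block, 4441, 7705, 9767 and 588 genes were called in P. yunnanensis and 1356, 4286, 5544 and 1918 in P. davidiana. The block changed no call of a named gene, and no count by over 1.5 times. Only in P. davidiana at 48 h against 0 h did every library correlate best with its own number. Over 36 results for 25 named genes, 621 of 636 values under alternatives kept direction and call, 15 lost the call and 0 reversed. Median ratio, quantile and TPM scaling changed no call of a named gene. The alternatives for gene lists were not run, because the lists could not be matched to identifiers. Depth was known only relative to 1 library, and fragment numbers only by taking the smallest step of low values as 1 fragment. Both limit what a value of 0 can exclude.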

Other observations

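The tests of genes that were off or on, of the kind of identifier, of genes at 0 with a minimum of 5 FPKM and of runs of genes were chosen after the data were seen. Genes below 0.5 FPKM in every 0 h library and at 5 FPKM or more in every 120 h library numbered 33 in P. yunnanensis and 63 in P. davidiana. In both lists were 5 genes, against 0.084 for independent lists. The reverse change was seen in 9 genes of P. yunnanensis and 5 of P. davidiana, with 0 in common. At a minimum of 5 FPKM in the other species, 23 genes were listed at 0 in every P. davidiana library and 3 in every P. yunnanensis library.

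At 120 h assembled loci changed over time less often than other genes did, by Fisher's exact test (two-sided) of each kind against the rest, adjusted over all kinds and comparisons, though genes are not independent. Here 23.6% of 554 assembled loci changed in P. yunnanensis, against 36.7% of the genes placed on chromosomes (adjusted p = 1.12e-09), and 9.57% against 20.05% in P. davidiana (adjusted p = 3.59e-10). They differed between the species at 0 h more often, at 50.5% against 40.9% (adjusted p = 3.49e-05). Genes on unplaced scaffolds moved the same way, with 27.3% changed at 120 h in P. yunnanensis (adjusted p = 1.24e-06) and 50.1% different between the species at 0 h (adjusted p = 5.97e-06), while 17.9% changed at 120 h in P. davidiana (adjusted p = 0.274). These p-values set each kind against all other tested genes, not against the share on chromosomes printed beside it. Of the 133 genes listed at 0 in P. davidiana, 22 were assembled loci, 13 lay on unplaced scaffolds and 98 on chromosomes.

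Genes next to each other in identifier order were tested for shared responses at 120 h. The log2 changes of neighbours correlated at 0.132 in P. yunnanensis and 0.163 in P. davidiana, where the highest of 1000 shuffles within chromosomes gave 0.0225 and 0.0213 (p = 0.001 each, the smallest that the shuffles can give). At 5 places apart the correlations were 0.0029 and 0.0246. One run of 10 tested genes in a row on chromosome 10 fell in P. yunnanensis at 96 and 120 h, and 6 of its genes in a row fell in P. davidiana at 120 h. At 120 h the longest runs of rises were 10 genes on chromosome 5 in P. yunnanensis and 9 on chromosome 11 in P. davidiana. Run lengths were not tested against chance. Reads shared between copies of a gene may give such neighbours the same change, as may common regulation, and the correlations of 0.132 and 0.163 do not tell these apart.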
